A study of Arabidopsis thaliana with 4 samples.

How the data were processed

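RNA from whole plants of Arabidopsis thaliana was measured on ATH1 arrays, which carry short oligonucleotide probes grouped into probe sets. The 4 arrays came from 4 groups with 1 array each: wild type (accession Ws-2) and the ku80 mutant, each with and without bleomycin. Each array held RNA pooled from 20 plants, so the pool averages over plants but gives no measure of the spread between pools. Per the labels, bleomycin was given at 1 mg per litre for 3 days, plants were at growth stage 1.06 and were grown at 23 °C with 16 hours of light, and cDNA was primed with oligo-dT.

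The deposited values were linear intensities, 1 per probe set and array, for 22810 probe sets. The mean after trimming 2% of values from each end was 100.01 on each array, so the deposited intensities had already been scaled to a common mean. Column medians were 45.7 and 40.0 in wild type without and with bleomycin, and 44.1 and 43.2 in ku80. The software that summarised the probes, its background correction and its version were not given in the sources used here. Scanner values per array, per the labels, were a mean background of 95.8 and a raw noise value Q of 3.33 for ku80 without bleomycin, and of 105 to 107 and 3.71 to 3.88 for the other 3 arrays.

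The 64 control probe sets were set aside, which left 22746. Each array was divided by a factor, the median ratio to the geometric mean of the 4 arrays over the brighter 50% of probe sets. The factors were 1.02 for wild type and 0.977 for wild type with bleomycin, and 1.00 for ku80 and 1.04 for ku80 with bleomycin. A floor was then set at the 40th percentile of all scaled values (intensity 28.0), lower values were raised to it, and log2 was taken. Between 59.2% and 60.6% of probe sets lay above the floor on each array. A probe set counted as measured when it lay above the floor on at least 1 array (15334 probe sets), and 11872 lay above it on all 4. A fold against a value at the floor is a lower bound and is given as "at least", while sizes from the fit are estimates made with the floor in place of lower values.

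Probe sets were named through the platform table paired with the series, with symbols updated by gene identifier from a RefSeq gene table (assembly TAIR10.1). That table listed 14016 gene probe sets: 13513 with 1 gene and 503 with several, while 8730 were unnamed here. Of the 13513, 13436 matched the gene table. Among measured probe sets 8351 (54.5%) had 1 gene, so counts cover all measured probe sets and gene names cover about that share. No probe set was paired with KU80 (AT1G48050) in the tables used, so the insertion was not checked by its transcript.

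With 1 array per group, the 4 pairwise comparisons have no replicate check and no p-value. Probe sets with a difference of at least 2-fold were counted. Named genes followed a rule fixed before the data were examined: in each pairwise comparison the 10 highest and 10 lowest differences of at least 2-fold among probe sets above the floor on both arrays, for the shared response the 15 genes per direction with the largest smaller response, for the difference of responses the 10 per direction, both among probe sets above the floor on all 4 arrays, all members of the fixed lists, and the 10 smallest adjusted p-values per direction in the additive fit. Not every gene so chosen is printed. Gene families and their members were chosen after the values were seen.

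The only test planned was an additive linear model with genotype and bleomycin, fitted with limma 3.58.1 in R 4.3.3 with an intensity trend and Benjamini-Hochberg adjustment at 0.05. Each factor level then holds 2 arrays, and the 1 residual degree of freedom is the difference between the 2 genotypes' responses. Spread estimated this way mixes noise with any real difference of responses, and p-values measure only the spread between these arrays. The fit also borrows spread from other probe sets of like intensity, weighted as 15.6 prior degrees of freedom against the 1 residual one. The SE of a single probe set is therefore mostly borrowed. On simulated arrays with normal noise of the spread seen at each expression level, 15334 probe sets and 200 changed ones, the additive bleomycin fit recovered 22.0% of log2 changes of size 1 and 97.0% of size 2, and it called 5 of 15134 unchanged probe sets. The simulated noise had 1 spread per expression level, equal on all 4 arrays, and no shift shared by a whole pool. On the real arrays the variance assigned to each array differed (0.029 to 0.214), in a split with no genotype part. The rate of false calls in the real fit is therefore not known from this.

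There were 18 gene lists fixed before the data were examined, plus plastid and mitochondrial genes. Of 291 listed genes 41 were named on the array and 35 were measured, so most lists rest on 1 to 5 genes. The median log2 difference of a list was placed among 10000 random lists of the same size matched on mean expression in 20 bins, with the brightest probe set per gene. Positions below percentile 2.5 or above 97.5 are reported as outside the random lists, as a description of these arrays. On simulated data with the same noise, independent between probe sets, 6.0% of unchanged lists of 5 fell outside. Of lists of 5 shifted by 1, 98.5% were found. Lists of fewer than 5 genes were not simulated, so these rates do not describe most of the fixed lists. The fixed rule for plastid genes used locus codes that the gene table did not hold, so genes that the table places on the plastid chromosome were taken instead. The rule for mitochondrial genes, also by locus code, matched no gene and was not replaced. Whether mitochondrial genes were measured is therefore not known from this.

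Alternatives fixed beforehand were the deposited scale, quantile normalization, floors at the 25th and 55th percentile, only plain probe sets naming 1 gene, a pseudocount equal to the floor, a 3-fold threshold, a brighter array of at least 4 times the floor, and, for the additive fit, no trend, robust variance, the other factor left out, probe sets above the floor on all arrays and no filter. Python 3.11.15 with numpy 2.4.6, pandas 2.3.3 and scipy 1.17.1 was used for all other steps, and matplotlib 3.10.9 for the figures.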

Results

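The series measured gene expression in Arabidopsis with and without bleomycin, a drug that breaks DNA strands, in wild type and in a mutant with a T-DNA insertion in KU80. KU80 is a subunit of the Ku complex, which binds DNA ends in non-homologous end joining. The series title names repair of DNA breaks in end joining mutants as its subject. There were 4 groups of 1 array each, and each array held RNA pooled from 20 whole plants. No group was replicated. Differences between single arrays are therefore given as values, and "rose" or "fell" is used only of genes called by the additive fit over all 4 arrays.

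In wild type, among named genes above the floor on both arrays, the largest differences under bleomycin included those of AT4G22960, whose scaled intensity was 30.1 without and 351 with the drug (11.7-fold higher), and AT3G60420, at 38.9 and 546 (log2 3.81). AT1G21520 was 8.54-fold higher, AT3G15650 was 7.49-fold higher and AT2G18600 was 6.86-fold higher. CHI (AT2G43570), annotated as a putative chitinase, was 6.08-fold higher, and AT4G10270 was 8.00-fold higher. Lower with the drug were AT4G24780 (14.3-fold), the expansin gene EXPA8 (9.42-fold), whose product belongs to a family that loosens cell walls, AT4G19430 (8.98-fold), AT1G12080 (8.85-fold), TBL45 (6.70-fold) and GH9B13 (5.88-fold), a glycosyl hydrolase gene. AT1G68490 was 5.82-fold lower and AT2G10940 was 5.60-fold lower. In all, 844 probe sets were at least 2-fold higher and 1286 at least 2-fold lower, of 15334 measured.

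In ku80, AT4G17470 was at 48.7 without and 849 with bleomycin (log2 4.12) and AT4G22610 was 13.9-fold higher (41.8 to 582). AT4G22960 was 6.22-fold higher, and UPOX (AT2G21640), which encodes a mitochondrial protein and is a marker of oxidative stress, was 6.07-fold higher. AT1G14960 was 5.89-fold higher, AT4G04460 5.59-fold and AT5G23830 5.58-fold. The plant defensin genes PDF1.2b and PDF1.2, markers of jasmonate and ethylene signalling, were 12.5-fold and 11.7-fold lower. PDF1.2 and PDF1.2b are close copies and the PDF1.2b probe set can bind related transcripts, so their separate values are uncertain. AT2G33850 was 8.33-fold lower, AT2G43620 7.98-fold, the transcription factor gene WRKY53 6.80-fold, AT4G18970 6.43-fold, TBL45 6.22-fold and EXPA8 6.07-fold. There were 382 probe sets at least 2-fold higher and 861 at least 2-fold lower.

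The responses of the 2 genotypes, which share no array, overlapped. At least 2-fold higher in both were 166 probe sets, against 21.0 for independent lists, and at least 2-fold lower in both were 376, against 72.2. Across probe sets, which are not independent replicates, the responses had a Pearson r of 0.47 and a Spearman rho of 0.44. Among genes above the floor on all 4 arrays, AT4G22960, AT4G04460, AT3G08990, AT3G15650, AT5G48020 and AT3G60420 led those higher in both. AT5G48020 was 5.31-fold higher in wild type and 4.29-fold in ku80, AT3G47540 5.68-fold and 3.61-fold, and AMY1, an alpha-amylase-like gene, was higher by 1.72 and 2.01 on the log2 scale. AT1G43910 was 3.36-fold and 3.33-fold higher and AT5G17760 3.71-fold and 3.24-fold. Lower in both were TBL45, EXPA8, AT4G18970 (4.84-fold and 6.43-fold), AT2G05790 (5.39-fold and 4.64-fold), the subtilase gene SBT1.3 (4.46-fold and 5.14-fold), the cytochrome P450 gene CYP71B22 (4.40-fold and 5.95-fold), AT5G48490 (6.18-fold and 4.03-fold) and the beta glucosidase gene BGLU28 (3.53-fold and 3.76-fold).

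**Figure D1:**
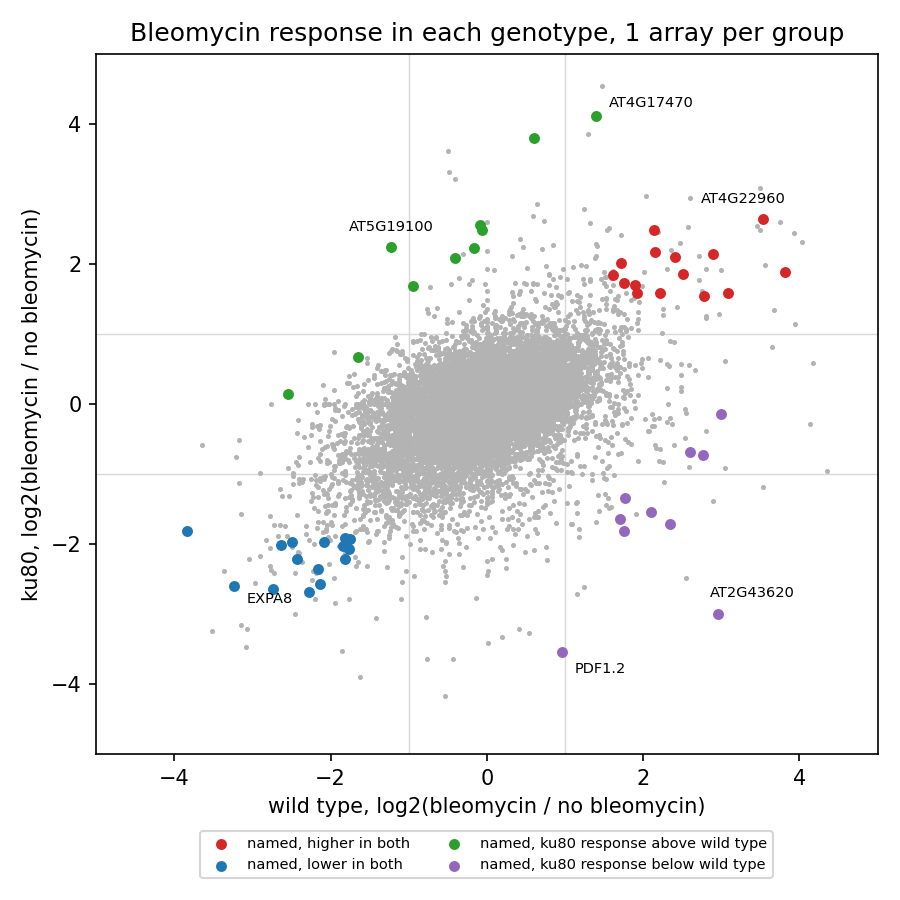
Log2 difference between bleomycin and no bleomycin in wild type (x axis) and in ku80 (y axis), 1 grey point per measured probe set, with genes named for the shared response and for the difference between responses in colour and lines at a 2-fold difference. EXPA8 lies low on both axes, and AT2G43620 lies at 2.96 in wild type and below 0 in ku80.

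In the additive fit, limma with Benjamini-Hochberg adjustment called 336 probe sets that rose and 700 that fell with bleomycin. AT4G22960 rose by 3.09 (log2, SE 0.31, adjusted p = 4.6e-05) and UPOX (AT2G21640), at the floor in wild type without the drug, by 3.17 (SE 0.32, adjusted p = 4.6e-05), higher in both genotypes. AT5G48020, AT3G60420, AT3G15650 and AT3G47540 also rose, by 2.18 to 2.84. AT5G60250, AT4G25330, AT3G45730 and ALPHA-VPE, which encodes a vacuolar processing enzyme, were at the floor on at least 1 array without the drug and rose by 2.32 to 2.55 in the fit. TBL45 fell by 2.69 (SE 0.29, adjusted p = 5.9e-05), and AT1G12080, AT4G29030, AT4G18970, EXPA8, AT2G05790, SBT1.3, AT4G38660, AT2G10940 and AT5G48490 fell as well. These calls depended on the settings of the fit: quantile normalization left 175 calls, all of them among the 1036, and leaving genotype out of the model left 0 in limma, with 2676 probe sets at an unadjusted p under 0.05.

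Few genes of the fixed lists were named and measured. Among the 35 in the 18 lists, limma called 7 for bleomycin over all genes tested, 4 that rose and 3 that fell, and 9 adjusted over the list alone, with the 35 genes taken as 1 list. For genotype it called 0 by either adjustment, and within single lists PDF1.2b, WRKY6 and SAG29 passed when adjusted over the list alone. Of the DNA damage response genes, MND1, a meiotic recombination gene at the floor without the drug, rose by 0.96 in the fit (adjusted p = 0.027), while LIG4, the ligase of end joining and the 1 measured member of that list, was 0.36 and 0.18 higher on the log2 scale in wild type and ku80 and was not called. Of the G2 and M phase genes, the mitotic kinase gene AUR1 fell (2.12-fold in wild type and 2.49-fold in ku80, adjusted p = 0.028), and AUR2 was lower by at least 0.28 and 0.55 and was called only when adjusted over the list alone. The median of these genes lay at percentile 0.8 of matched random lists in ku80 and 10.8 in wild type. SAG101, a defence and senescence gene, rose by 1.62 (adjusted p = 0.012) and SAG29 by 1.31 (adjusted p = 0.017). THI2.1, at the floor with the drug, fell by 0.91 in the fit (adjusted p = 0.038) and PDF1.2b by 2.21 (adjusted p = 0.0078), although PDF1.2b was only 1.70-fold lower in wild type. PDF1.2, of the same list, was 1.95-fold higher in wild type and 11.7-fold lower in ku80, and was not called. The photosynthesis gene SBPASE was lower in both genotypes (-1.02 and -0.92) and was not called over all genes (adjusted p = 0.089). The S phase gene MCM7 was at -0.16 and -0.36, and the clock gene GI at -0.95 and 0.01. The salicylic acid and cell death genes WRKY53 and SAG101 lay at -0.14 and 2.34 in wild type (median percentile 98.1) and at -2.77 and 0.90 in ku80 (median percentile 2.5), so their medians describe neither gene. The oxidative stress genes UPOX and GSTU25, both at the floor in wild type without the drug, were higher by at least 3.75 and 2.26 in wild type (median percentile 100.0). In ku80 they lay at 2.60 and -0.83 (median percentile 97.9), so that median describes neither gene. The median of the senescence genes lay at percentiles 97.7 and 90.6. Medians of the DNA damage, end joining, S phase, clock, photosynthesis, root, flavonoid and reference lists lay within the random lists in all 4 comparisons. The end joining, S phase and clock lists held 1 measured gene each, and the flavonoid list 2. Random ranges for 1 gene were wide, from -1.91 to 1.31 for the S phase list in wild type. Lying within them does not show that these processes were unchanged. No recombination and damage signalling gene or flower and seed gene was measured. For the DNA damage list, 2 of 26 genes were measured, and the bleomycin medians lay at percentiles 93.1 in wild type and 96.9 in ku80. With MND1 at the floor without the drug these medians are lower bounds, so they do not show that a DNA damage response was absent.

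The plastid genes had lower medians with bleomycin, -0.41 in wild type and -0.58 in ku80, both at percentile 0.0, and 53 and 63 of 68 genes were below 0. Of the 68, limma called 7 that fell and 0 that rose, among them ndhE, rpoC1, rpoC2, ndhH and psbD. ndhE was at 556 and 132 in wild type without and with the drug, and at 572 and 281 in ku80. The plastid medians of ku80 against wild type were 0.37 without and 0.11 with the drug, both at percentile 100.0. The 68 genes may move together on an array, which random lists drawn from all measured probe sets do not allow for. cDNA was primed with oligo-dT, and plastid transcripts mostly lack stable poly(A) tails.

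Without bleomycin, among named genes above the floor on both arrays, ku80 differed from wild type most at AT2G43620, at 811 against 31.4 (25.8-fold higher). AT1G30700 was 19.4-fold higher in ku80, AT4G33720 14.7-fold, PDF1.2 10.4-fold, CHI (AT2G43570) 10.4-fold, and the asparaginase gene ASPGB1 9.50-fold. AT1G33055, AT2G41730 and AT2G38870 were 8.84-fold, 8.80-fold and 8.19-fold higher (the AT2G41730 probe set can bind related transcripts and is uncertain), and GH3.3, of a family that conjugates amino acids to hormones, 7.36-fold. Lower in ku80 were AT4G17470 (7.72-fold), AT1G14960 (7.69-fold), AT3G26460 (5.58-fold), HIS1-3, a linker histone gene (5.32-fold), AT4G26010 (4.78-fold), ORA47 (4.34-fold) and AT4G22610 (4.25-fold). The jasmonate and ethylene defence genes had a median of 2.77 over 3 genes, with PDF1.2 and PDF1.2b higher and THI2.1 lower (-0.70). The heat shock genes had a median of 0.73 over 4 genes (percentile 100.0), which lay within the random lists with the higher floor (0.16). The senescence genes WRKY6 and SAG29 were higher by 1.14 and 1.45, and the oxidative stress genes GSTU25 and UPOX by at least 2.51 and 1.33. There were 388 probe sets at least 2-fold higher and 320 lower. Bacterial spike-in controls were dimmer on the wild type array without bleomycin than on the other 3 arrays, by 1.31-fold to 1.63-fold.

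With bleomycin, ku80 was higher than wild type at AT5G19100 (4.67-fold), AT1G68490 (4.54-fold), AT1G74010 (3.86-fold), AT2G15220 (3.66-fold, a probe set that can bind related genes and is uncertain) and AT1G30700 (3.58-fold). It was lower at ORA47 (11.4-fold), a gene of the ethylene response factor family, at AT3G01830 (8.53-fold), AT1G19210 (6.49-fold), AT1G58420 (6.12-fold), AT5G66650 (5.16-fold), AT1G05575 (5.00-fold), AT4G27654 (4.96-fold), AT4G29780 (4.75-fold), AT3G02840 (4.67-fold) and AT2G25735 (4.49-fold). WRKY53 was 4.36-fold lower, and the zinc finger gene ZAT10 (STZ), the 1 measured touch and early stress gene, was at 740 in ku80 and 2048 in wild type (percentile 0.1). COR47 and LTI30, of the abscisic acid, drought and cold list, were lower, with a median of -0.80 (percentile 1.1). In all, 286 probe sets were at least 2-fold higher and 360 lower (44.3% higher). On the deposited scale 57.2% were higher and with the 3-fold threshold 24.8%, so the balance of directions turned with the settings.

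The 2 genotype comparisons, which share no array, had a Pearson r of 0.07 and a Spearman rho of 0.03 across probe sets. Higher in both were 34 probe sets, against 7.2 for independent lists, and lower in both 36, against 7.5. In opposite directions, 27 were higher without and lower with bleomycin, against 9.1, and 8 the reverse, against 6.0. For genotype, limma called 21 probe sets that rose and 13 that fell in ku80. AT2G15220 rose by 2.30 (adjusted p = 0.0016), the jasmonate-regulated gene JRG21, at the floor on both wild type arrays, by 2.70 (adjusted p = 0.0016), AT1G30700 by 3.06 (adjusted p = 0.0022) and CCOAMT, a caffeoyl-CoA methyltransferase gene at the floor in wild type without the drug, by 2.47 (adjusted p = 0.0091). AT1G26390 and AT1G26380, also at the floor there, rose by 2.77 and 2.48 in the fit. These sizes average unlike differences. Without and with bleomycin, AT1G26390 was higher by at least 3.98 and by 1.55, and AT1G26380 by at least 3.88 and by 1.08. ORA47 fell by 2.81 (adjusted p = 0.00068), and AT1G19210, AT1G23130, AT5G66650 and AT2G42760 fell by 1.45 to 2.02. Quantile normalization and the fit without an intensity trend left 0 calls in limma, with 888 and 926 probe sets at an unadjusted p under 0.05.

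Among genes above the floor on all 4 arrays, the difference between the responses was most negative, that is lower in ku80, at AT2G43620 (-5.95), PDF1.2 (-4.51), AT1G19530 (-4.07), AT4G33720 (-3.63), GH3.3 (-3.57), AT4G39670 (-3.50), AT5G64100 (-3.35), CHI (-3.29), AT4G10270 (-3.14) and AT1G58420 (-3.11). It was most positive at AT5G19100 (3.47), AT4G22610 (3.18), AT4G17470 (2.72), AT1G68490 (2.69), AT1G14960 (2.65) and HIS1-3 (2.62). For most of these genes the arrays without bleomycin differed more than the arrays with it: CHI was at 35.1 in wild type and 365 in ku80 without the drug, and at 213 and 226 with it. The difference was at least 1 (log2) at 834 probe sets and at most -1 at 821, 50.4% positive, with 62.8% on the deposited scale and 37.6% with the 3-fold threshold. With 1 array per group no residual was left to test this difference. A fit in limma that took the bleomycin effect as the residual called 0 probe sets, with 96 at an unadjusted p under 0.05, and that residual holds the large response to the drug.

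**Figure D2:**
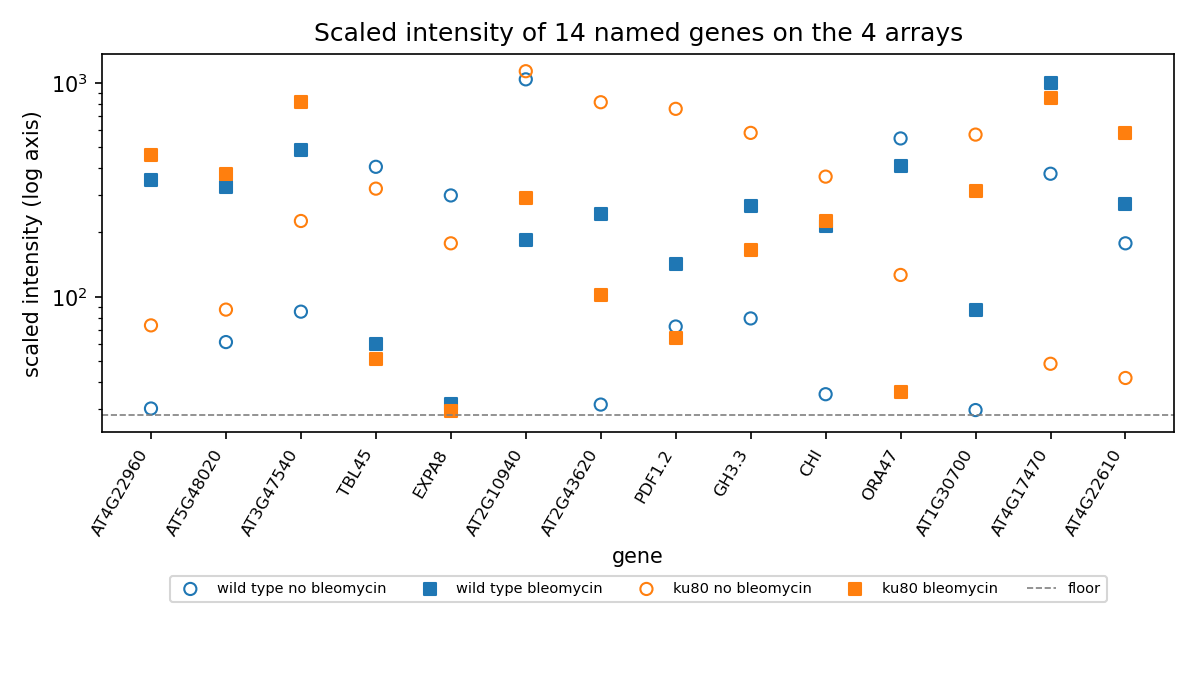
Scaled intensity (log axis) of 14 genes named by the fixed rule, 1 marker per array, with open circles for no bleomycin, filled squares for bleomycin, blue for wild type, orange for ku80 and a dashed line at the floor of 28.0. TBL45 and EXPA8 are lower on both bleomycin arrays, while AT2G43620 stands highest on the ku80 array without the drug, at 811.

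As a control of RNA quality, the 3' to 5' ratio lay between 1.09 and 1.19 for GAPDH, between 1.24 and 1.38 for actin, and for ubiquitin at 1.17 and 1.21 in wild type and 1.42 and 1.53 in ku80. Across probe sets, the array of ku80 without bleomycin had a Pearson r of 0.938 with wild type without bleomycin, 0.923 with wild type with bleomycin and 0.921 with ku80 with bleomycin.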

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

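The tests in this part, other than quantile normalization, were chosen after the results were seen. Of the genes named for the difference between responses, 7 were at least 2-fold higher with bleomycin in one genotype and at least 2-fold lower in the other. These differences were not tested against a residual of their own, since 1 array per group leaves none, and the fit in limma that took the bleomycin effect as the residual called 0. The difference of log2 responses, ku80 minus wild type, was 3.47 at AT5G19100, -5.95 at AT2G43620, -4.07 at AT1G19530, -3.63 at AT4G33720, -3.57 at GH3.3, -3.35 at AT5G64100 and -3.11 at AT1G58420. Over all measured probe sets, 36 were 2-fold higher in wild type and 2-fold lower in ku80, against 47.4 for independent lists. Only 1 was the opposite, against 32.0. The 2 responses were correlated (Pearson r 0.47), which lowers opposite counts below those of independent lists. The comparison therefore cannot show whether opposite responses were unusual.

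AT2G43620, AT1G19530, AT4G33720, GH3.3 and AT5G64100 were also at least 2-fold higher in ku80 than in wild type without bleomycin. Forcing the arrays to 1 distribution left 98.2% of the number of 2-fold probe sets. This argues against a difference in the distribution of brightness as the source of that number only. It does not show whether the same probe sets stayed 2-fold different. Random lists matched to the bright plastid genes also lay above 0 in this comparison (0.05 to 0.25), so a shift of bright probe sets stays open. Degraded RNA stays open: the largest ratio between arrays in a 3' to 5' control was 1.3, but that control, ubiquitin, was higher on both ku80 arrays and the ratios have no spread. The wild type array without bleomycin standing apart stays open too: its SD from the mean of the other 3 arrays was the highest, 1.17 times the next. It also had the largest variance of its own, 0.214. The next highest was 0.111, in ku80 with bleomycin, and ku80 without bleomycin had 0.029. These variances came from a split with no genotype part, so they hold any real genotype difference as well as array noise. The spike-ins of the wild type array without bleomycin were dimmest, and it is the only untreated wild type sample. That array cannot be told apart from its group, the array of ku80 without bleomycin had the lowest scanner background (95.8), and a difference between pools in growth or handling was not tested.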

How the results depend on the processing

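The alternatives that leave out 1 array were chosen after seeing the data. No paired analysis was possible because the labels pair no samples beyond genotype and bleomycin, which the additive fit holds as factors. Counts are of probe sets in the order wild type response, ku80 response, ku80 against wild type without and with bleomycin, and difference between responses, then the shared response, where a count moved by over 1.5 times. The main counts were 2130, 1243, 708, 646, 1655 and 542. With plain probe sets naming 1 gene they were 1062, 600, 344, 300, 837 and 253, since fewer probe sets entered. With the pseudocount they were 1315, 768, 456, 321, 961 and 290, and with the 3-fold threshold 558, 352, 258, 125, 431 and 127. With a brighter array of at least 4 times the floor, 1414, 465, 422 and 1052 remained for the wild type response, the 2 genotype comparisons and the difference. The lower floor gave 1013 for ku80 against wild type with bleomycin and 2615 for the difference. The deposited scale, quantile normalization and the higher floor kept these counts within 1.5 times.

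The additive calls were the least stable. For bleomycin (1036 calls) limma gave 175 with quantile normalization, 256 with plain probe sets, 466 without the trend, and 0 with no filter (1937 at an unadjusted p under 0.05) or with genotype left out (2676). For genotype (34 calls) it gave 12 with the lower floor, 2 with plain probe sets, 72 with the pseudocount, 104 with probe sets above the floor on all arrays and 11 with robust variance. It gave 0 with quantile normalization (888), without the trend (926), with no filter (657) and with bleomycin left out (289). Leaving out each array in turn, together with the other factor, gave from 0 to 0 calls for either factor, with 1658 to 2658 and 324 to 1166 at an unadjusted p under 0.05. Those fits assume that the lone array of a level varies like the others. The SE of each probe set leaned on spread borrowed from other probe sets, weighted by prior degrees of freedom. For bleomycin this weight was 15.6 in the main fit and 9.9 with plain probe sets. It was 6.8 without the trend, 5.9 with quantile normalization and 1.0 with no filter. Large drops in bleomycin calls thus went with less borrowing, but robust variance gave fewer calls (753) at 15.6. Apart from this and the fewer probe sets tested, the cause was not examined.

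Among alternative values of single named genes, 435 moved by less than 1 SD of that comparison and 65 by more, with 0 changes of sign. Among alternative values of gene lists with at least 3 genes, 280 kept their position, 6 moved outside the random lists and 1 moved within them. The plastid genes' difference between responses was -0.14 at percentile 99.5, above the random lists, which ran from -0.49 to -0.20. Its sign reversed to 0.20 with quantile normalization, still above the random lists. Probe sets of like brightness thus lay below 0 in the main setting, so the sign of the plastid median is not separate from that shift. The cause of the shift was not tested. Values near the floor limit dim genes.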

Other observations

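Families were formed after the data were seen from the letters that open gene symbols, with at least 6 measured members, which gave 34 families and 204 comparisons. Of these, 43 lay outside the central range of matched random lists used for the fixed lists, against 10.2 by chance if comparisons were independent, which they are not. Of the 43, 9 came from the RPL and RPS families, whose measured members were all plastid genes, so they count the plastid shift again. The plant U-box ubiquitin ligase genes (PUB) had a median difference between responses of -1.26 over 8 genes, with PUB23 and PUB22 at -1.94 and -1.90, but PUB43 was at 0.49, and PUB25 and PUB26, at the floor on several arrays, at 0.86. PUB23 was 0.52 lower in wild type and 2.46 lower in ku80 on the log2 scale. The calmodulin-like genes (CML) had a median difference of -1.07 over 7 genes, with CML42 at -1.65, but CML43 was at 0.24 and CML30, at the floor on the wild type array with bleomycin, at least at 0.83. Expansin genes (EXPA) had medians of -0.97 in wild type and -0.39 in ku80 over 8 genes, and EXPA4 was at -1.45 and -1.11, while EXPA7, at the floor on 3 arrays, was higher by at least 0.19 in wild type. Tau class glutathione transferase genes (GSTU) had a median of 0.72 for the mean of the 2 responses over 9 genes, but GSTU25 was at 2.26 or more in wild type and -0.83 in ku80, and GSTU26 at -0.08 and at least 2.58. The ubiquitin-specific protease genes (UBP) had a median of 0.60 for ku80 against wild type with bleomycin over 12 genes, with UBP19 and UBP20 at -0.62 and -0.15. No member above the floor on both arrays reached 2-fold. UBP21, UBP26 and UBP27, at the floor in wild type with bleomycin, were higher by at least 0.74, 0.67 and 0.04.

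A hypothesis, formed and tested after the data were seen, was that ku80 without bleomycin may already carry part of the bleomycin response. Among the 166 probe sets 2-fold higher with bleomycin in both genotypes, the median difference of ku80 from wild type without the drug was 0.33, and 121 were higher in ku80. Among the 376 that were 2-fold lower it was -0.33, and 309 were lower in ku80. Choosing genes on these same arrays gives part of such a shift. In 200 simulations with no genotype effect and the arrays' own variances, medians ran from 0.06 to 0.27 and from -0.25 to -0.07. Those variances came from a split with no genotype part, so any real genotype difference was counted in them as array variance. The simulated ranges are thus not free of the effect in question. The observed values lay just beyond those ranges, so the hypothesis is a candidate only. With bleomycin the same 166 were also higher in ku80, with a median of 0.22 beyond the simulated -0.02 to 0.16, while the 376 lower ones had a median of -0.13, within the simulated -0.15 to 0.00. Whether the shift was limited to plants without the drug thus differed between the sets. It is not separate from the untreated wild type array standing apart (SD ratio 1.17, own variance 0.214). Standing apart would give the same sign, and replicated untreated pools would be needed.

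With 4 arrays there are 3 splits into 2 pairs, too few for a share under 0.05. The split by bleomycin gave 1036 calls in limma, and the highest other split, by genotype, gave 34. The number of splits with at least 1036 calls was 1, the bleomycin split itself. The remaining split was fitted with the bleomycin effect as its residual, so the counts of the 3 splits are not on equal terms.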
